A study of Arabidopsis thaliana with 20 samples.

How the data were processed

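The study measured RNA levels in rosette leaves of Arabidopsis thaliana with 1-colour arrays. Leaves came from wild-type plants (WT) and from Atss3, a mutant in starch synthase 3, all grown with 8 h of light and 16 h of darkness. Per the labels, total RNA was labelled with biotin, and each of the 20 arrays measured the pooled leaves of 16 plants. Groups were taken from the sample titles: 2 genotypes by 5 harvest times after the lights came on (1 h and 4 h in the light, then 8.5 h, 12 h and 16 h in the dark), with 2 arrays in each of the 10 groups. Per the labels, the whole experiment was done 2 times with separate randomizations, and the replicate number marks the run.

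The deposited values are linear signal intensities, 1 per probe set (a group of oligonucleotides designed for 1 transcript or a few). Per the submitters' processing notes they were made with MAS5, and the version is not given in the sources used here. The 2% trimmed mean of the deposited intensity values was 499.8 on each array, so the table had already been scaled to a common mean by the authors and was used as deposited. A scaling of this kind sets the average array signal equal, so a change in total RNA cannot be seen. Median signals ran from 151.7 to 178.4 per array and maxima from 21950 to 37924. For arrays such as these, the number of arrays limits the precision of each value.

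Of 22810 probe sets, 64 controls were left out, and 22746 remained. Values under 1 were raised to 1 (95 to 245 values per array), and log2 was taken. A probe set was kept if it exceeded its array's 40th percentile on at least 2 arrays, which left 15470. Gene names came from a platform annotation table that listed 14016 probe sets, 13513 with 1 gene and 503 with several, while 8730 were not listed and stay unnamed here. Of the probe sets with 1 gene, 13436 matched the gene table of assembly TAIR10.1 by Entrez gene identifier, from which symbols were updated. No coordinates were used. Kept probe sets with 1 gene numbered 8511, and 98 genes had several of them. Where a gene stood in a list or family with several probe sets, the probe set with the highest mean log2 signal was used. No named probe set was tied to SS3, so the planned signal of the mutated gene was not analysed here, and the mutant label was not checked through it.

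Linear models were fitted in limma 3.58.1 (R 4.3.3). The model had a mean for each of the 10 groups and the run as a block, with 9 residual degrees of freedom and 3.45 prior degrees of freedom from empirical Bayes moderation. P-values are 2-sided and were adjusted by Benjamini-Hochberg over all kept probe sets within each contrast, with a threshold of 0.05. Contrasts were Atss3 minus WT over the 5 times, Atss3 minus WT at each time, the genotype by time interaction (a moderated F test over 4 differences), the time course in each genotype, and dark minus light. Dark minus light was the mean of 12 and 16 h minus the mean of 1 and 4 h, so darkness and time of day cannot be told apart in it. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.

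Gene sets were tested with camera at a preset correlation of 0.01, adjusted over the sets within a contrast, and with an estimated correlation and fry as alternatives. There were 23 lists of genes fixed from general knowledge before the data were examined, with 352 entries, of which 54 had a named probe set; of 330 distinct loci, 45 were measured in a kept probe set. The 9 lists with at least 3 measured members were tested. A further 32 families were defined by their gene symbols, and all 32 were tested. The lists, the model, the contrasts, the filter and the rule for named genes were also fixed at that stage. The 32 families were fixed later, once the array annotation was in hand and before any group values were looked at.

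The rule for named genes took QQS and SS3 always. QQS was chosen because it is known to have been singled out from these plants, so its result is no independent evidence. For the genotype effect over the day it took up to 10 rises and 10 falls past the threshold that name 1 gene and have the same sign in at least 9 of 10 pairs of arrays of the same time and run. At each time it took up to 3 rises and 3 falls with the same sign in both runs, for the interaction the 6 smallest p-values, and for dark minus light the 8 largest rises and 8 largest falls in WT. For each list it took the 3 called members with the smallest p, or 2 if none was called. Only QQS passed the rule for the genotype effect over the day. The genes named beside it as nearest to the threshold, and the probe sets 262809_at, 245882_at and 266932_s_at, were chosen after their values were seen.

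Samples that share a run number were checked for pairing. Deviations from the group means correlated above 0.1 in 41 of 45 pairs of groups, with a median of 0.20 and a range from -0.11 to 0.44; between the genotypes at the same time they ran from 0.18 to 0.40. The numbers pair the samples because the labels tie them to a run. Replicate arrays of a group correlated at 0.948 to 0.967 over log2 values and had 0 identical values. Growth and harvest were randomized separately for each run. The run was a block in the model, so the mean difference between the runs was removed. The p-values reflect the scatter that remained among the pooled samples, with the pairs of a run treated as independent. They do not fully cover a genotype effect that varies from run to run, and a difference of that effect between the runs was called for 83 probe sets.

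The scripts were tested on simulated data with 15470 probe sets and 200 changed probe sets at each size. Over the day, 59% were recovered at a log2 change of 0.5, 97% at 1 and 99% at 2. At 1 h alone, 0% were recovered at 0.5, 34.5% at 1 and 93.5% at 2. For dark minus light in WT, 0% were recovered at 0.5, 82.5% at 1 and 97.5% at 2. For the interaction, 0% were recovered at 0.5, 0% at 1 and 77.5% at 2. A set of 15 members shifted by 0.3 over the day was found in 20 of 20 simulations, and 0 of 380 other sets were called. The simulated noise was independent between probe sets, the sets were random, and no difference of the genotype effect between runs was simulated. These counts therefore do not show how often camera calls families of correlated genes falsely.

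Alternatives chosen with the lists were the fit without the block, the run as a random block, quantile normalization, centring on array medians, 16 or 64 added before log2, no filter, only the brighter probe sets, an intensity trend, an additive model, each run alone, and each array left out in turn. Alternatives added after seeing the data were the GAPDH 3' to 5' control ratio as a covariate, a threshold of 0.1, signals under each array's 40th percentile raised to it, the 5 WT arrays of run 1 left out, and all settings for the families. A signal under its array's 40th percentile is called dim here, and no detection calls were used. Where both groups are dim, a difference of raised signals reflects only the percentiles of the arrays. The 8.5 h arrays were left out of dark minus light because they came soon after the lights went off.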

Results

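Transcript levels were measured in rosette leaves of WT and Atss3 plants at 5 times of a day with 8 h of light. Atss3 lacks normal function of starch synthase 3, an enzyme that builds the glucan chains of leaf starch. The series compared the genotypes over the day, with 2 arrays for each genotype and time and 10 arrays per genotype in all. Time set most of the variation: the first principal component held 43.1% of it and harvest time explained 99% of that component. Run explained 20.3% of the third component (9.8% of the variation) and 54.6% of the fourth (5.4%). Genotype explained 41.5% of the fifth component, which held 4.1%. On it the WT arrays of run 1 lay from -24.7 to -13.3. Those of run 2 lay from -13.3 to 8.4 and overlapped the Atss3 arrays, at -11 to 37.5.

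QQS (AT3G30720), a short gene known to have been singled out from these plants, was 11.5-fold higher in Atss3 over the day. Its signal was 3546 ± 1228 in Atss3 and 324 ± 143 in WT (mean ± SD, n = 10 arrays each), and it was higher in 10 of 10 pairs of arrays of the same time and run. The log2 difference was 3.52 (SE 0.148, adjusted p = 1.42e-07), with 3.66 in run 1 and 3.38 in run 2. An unnamed probe set, 262809_at, was lower in Atss3 by -2.30 log2 (SE 0.108, adjusted p = 2.99e-07), with signals of 126 ± 20.8 in Atss3 and 651 ± 237 in WT (SD, n = 10 each) and the same direction in 10 of 10 pairs. A further unnamed probe set, 245882_at, was higher by 0.86 log2 (SE 0.119, adjusted p = 0.0409, 10 of 10 pairs), with signals of 102 ± 39.7 and 55.6 ± 19.6, but it was dim (under its array's 40th percentile) on 16 of 20 arrays and lost the call with signals raised to that percentile (0.31 log2). The mutated gene itself, SS3, was not analysed here because no named probe set was tied to it. An unnamed probe set may still measure SS3, and whether 262809_at does was not known here.

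**Figure D1:**
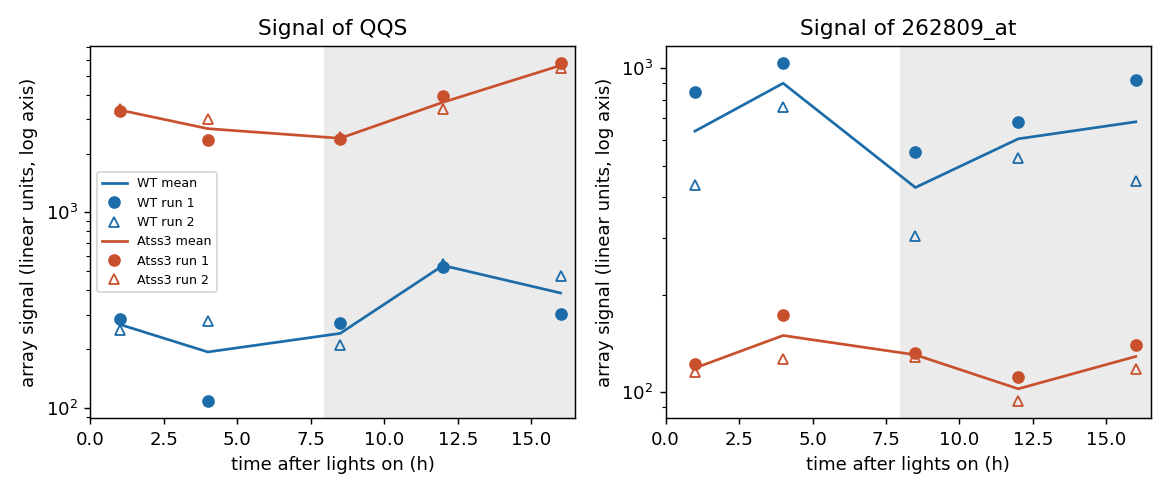
Array signal of QQS and of probe set 262809_at (linear units, log axis) against hours after lights on, with a point per array, lines at the group means of 2 arrays, and the dark period shaded. QQS lay between 2352.7 and 5824.4 on the Atss3 arrays and between 107.9 and 547.3 on the WT arrays, and 262809_at between 93.6 and 172.7 against 304.2 and 1039.9.

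These were the 3 probe sets called among 15470 in limma, 2 higher and 1 lower. An unadjusted p under 0.05 was reached by 2123 (13.7%), of which 1267 were higher and 856 lower, against 774 for chance. Fitted alone, run 1 gave 2781 such probe sets and run 2 gave 1088. The named genes nearest to the threshold did not pass it. AT3G23880 differed by -0.59 log2 (SE 0.089, 9 of 10 pairs, adjusted p = 0.0502). AT1G49200 (-0.61, and -0.29 with raised signals) and AT2G04460 (0.84, and 0.33) had the same adjusted p. DI19, a zinc finger gene of drought responses, differed by -0.48 (SE 0.077, adjusted p = 0.0695, 10 of 10 pairs). COR27 (AT5G42900), a cold-regulated gene tied to the clock, differed by -0.997 (SE 0.185, but from -1.31 to -0.22 over the alternatives, the smallest with raised signals, since it was dim on 4 of 4 light arrays in each genotype) and CSLA01, a member of the cellulose synthase-like family that makes mannan, by 1.21 (SE 0.216), both with adjusted p = 0.103. Call counts differed by run: run 1 alone called 86 probe sets (76 higher) and run 2 alone called 2, with 1 called in both, and across genes the differences of the runs correlated at 0.042 (genes are not independent replicates). 262809_at lost its call in run 2 alone (-2.04 log2, adjusted p = 0.0628), and 245882_at lost it in run 1 alone (0.87 log2, adjusted p = 0.182), in run 2 alone (0.86 log2, adjusted p = 0.566) and without the run block (0.86 log2, adjusted p = 0.177).

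The few starch genes measured showed no called difference between the genotypes. Only 3 of 16 listed starch synthesis genes and 3 of 23 listed starch breakdown genes had a named probe set that was kept. The other listed starch genes were not assessed. Of the 9 lists tested with camera, 0 were called for the genotype effect, and 0 members were called over all genes. Among starch synthesis genes, APL3, a large subunit of ADP-glucose pyrophosphorylase, differed by 0.32 log2 (SE 0.070, adjusted p = 0.122, 8 of 10 pairs), and 1 of 3 members passed when adjusted over the list alone. The list gave a camera adjusted p of 0.229 and a median of 0.09, with medians of 0.02 in run 1 and 0.26 in run 2. Starch breakdown genes had a median of 0.04 (adjusted p = 0.856, and -0.03 with arrays centred on their medians), with DPE1, the plastid disproportionating enzyme, at -0.06 (SE 0.087) and 0 of 3 passing when adjusted over the list alone. The anthocyanin and flavonoid list had a median of 0.54 (adjusted p = 0.229), with DFR, which reduces dihydroflavonols, at 0.65 (SE 0.249, adjusted p = 0.295) and 0 of 3 passing when adjusted over the list alone.

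The remaining 6 lists also gave no call. Medians were -0.01 for sucrose metabolism and transport (adjusted p = 0.756), -0.03 for genes induced by carbon starvation (0.612) and 0.08 for light harvesting and photosystems (0.532, and -0.02 after quantile normalization). They were 0.08 for the Calvin cycle (0.532, and -0.01 after quantile normalization) and -0.25 for cold and abscisic acid response (0.229). The senescence median was 0.21 (0.274), and 0.11 with raised signals (camera adjusted p = 0.523). When adjusted over the list alone, 1 of 3 cold and abscisic acid genes passed (COR15A, -0.28, SE 0.077), 1 of 3 senescence genes passed (SAG101, 0.38, SE 0.135), and 0 passed in the other 4 lists. Markers of other leaf or plant parts did not pass either: the root marker PYK10 differed by 0.09 (adjusted p = 0.859), the guard cell gene FMA by -0.07 (0.742) and SWEET11, a sucrose exporter of the vasculature, by -0.03 (0.921).

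Of 4 families of plastid-encoded genes 2 were called as higher in Atss3, and cold and dehydration genes were called as lower. All 3 calls were lost with an estimated correlation. They were also lost without Atss3 16 h replicate 1. The photosystem median was 0.28 (adjusted p = 0.0713), the ribosomal and polymerase median 0.30 (0.304) and the cold median -0.26 (0.0713). In camera, 20 plastid photosystem genes had a median of 0.39 log2 (adjusted p = 0.00156 over 32 families; p = 0.211 with an estimated correlation), with 19 of 20 above 0. The 19 plastid ribosomal protein and RNA polymerase genes had a median of 0.36 (adjusted p = 0.0129; p = 0.225 with an estimated correlation), with rps19 at 0.60 (SE 0.151, adjusted p = 0.158) and rpl20 at -0.68 (SE 0.138, adjusted p = 0.103). The 9 NDH complex genes (median 0.25, adjusted p = 0.173) and the 12 cytochrome and ATP synthase genes (median 0.24, adjusted p = 0.065) were not called, but both were after quantile normalization (0.0446 and 0.0218) and with arrays centred on their medians (0.0231 and 0.0136). Without the 5 WT arrays of run 1 the direction turned. The medians were -0.16 for the photosystem, -0.73 for the NDH, -0.43 for the cytochrome and ATP synthase and -0.07 for the ribosomal and polymerase genes. With the run as a block this fit gives the differences of run 2 alone, so it is no separate evidence beside that run. With the GAPDH 3' to 5' ratio as a covariate these medians were -0.13, -0.55, -0.39 and 0.01, and the NDH and cytochrome and ATP synthase genes were called as lower (adjusted p = 0.0459 each). The runs differed: over 60 plastid-encoded genes of 4 families the median was 0.99 in run 1, with 53 above 0, and -0.22 in run 2, with 13 above 0. Mitochondrial genes had medians of 0.43 and -0.18 in the runs and were not called (11 genes, adjusted p = 0.561). The log2 ratio of the 3' to the 5' GAPDH control signal, a measure of RNA integrity and labelling, also differed by genotype and run. It was -0.13 ± 0.109 on the 5 WT arrays of run 1 (SD, n = 5), and 0.30 ± 0.093, 0.38 ± 0.034 and 0.43 ± 0.203 on the WT arrays of run 2 and the Atss3 arrays of runs 1 and 2. The actin 3' to 5' ratio showed no such difference by genotype (Atss3 minus WT -0.198 log2, exact permutation p = 0.352).

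The 9 cold and dehydration genes had a median of -0.25 log2 (camera adjusted p = 0.0129; p = 0.0498 with an estimated correlation, adjusted p = 0.967), with 2 of 9 above 0 in each run and medians of -0.27 in run 1 and -0.21 in run 2. With arrays centred on their medians the median was larger, -0.32 (SD of the members 0.366 in both), and the call was lost (adjusted p = 0.052). Other genes moved down too: the mean t of all genes went from 0.193 to -0.441. Of its members 0 of 9 were called over all genes and 2 of 9 passed when adjusted over the family alone. COR15A, which protects chloroplast membranes in the cold, differed by -0.28, and COR27 by -0.997, on dim light signals. XERICO, a gene of abscisic acid accumulation, differed by -0.25 (SE 0.112), with a pair of 8.5 h run 1 at -1.19 set apart from the rest. Without the 5 WT arrays of run 1 the family was not called, and its median, -0.21, was that of run 2 alone.

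**Figure D2:**
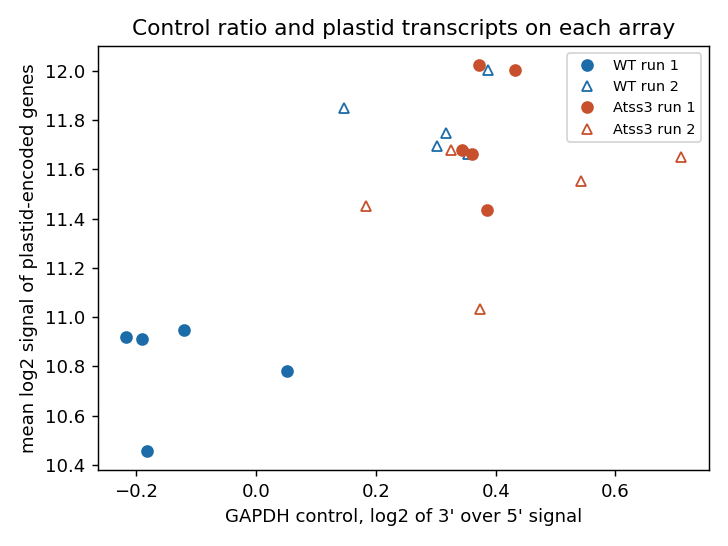
Mean log2 signal of 60 plastid-encoded genes against the log2 ratio of the 3' to the 5' GAPDH control signal, with a point per array and a colour and shape for each genotype and run. The 5 WT arrays of run 1 had ratios from -0.22 to 0.05 and a mean plastid signal of 10.80, against 11.79, 11.76 and 11.47 for the WT arrays of run 2 and the Atss3 arrays of runs 1 and 2.

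At 1 h into the light, QQS was higher in Atss3 by 3.65 log2 (SE 0.330, adjusted p = 7e-04) and AT1G72060 by 1.69 (SE 0.268, 0.0358). In all 17 probe sets were called, 9 higher and 8 lower in Atss3. Of these, 8 of the 17 lay under their array's 40th percentile on all arrays of 1 h, and with signals raised to that percentile 7 of the 17 kept the call. AT1G77030 (2.40, SE 0.332), AT3G19330 (-2.65, SE 0.287) and NRPD7, a subunit of the plant RNA polymerase of gene silencing (-1.10, SE 0.157), were dim in this sense on 2 of 2 arrays of each genotype, and AT5G63480 (-2.61, SE 0.283) on 1 of 2 in WT and 2 of 2 in Atss3. Their adjusted p-values were 0.0151, 0.00197, 0.0171 and 0.00197 as deposited and 0.937, 0.936, 0.932 and 0.955 with raised signals (log2 differences of 0.08, 0.08, 0.08 and -0.06), so no difference in these genes is shown. An unadjusted p under 0.05 was reached by 1424. The balance of directions was not stable: it was 8 higher and 13 lower with arrays centred on their medians, 43 and 49 without WT 1 h replicate 1, 19 and 8 without WT 1 h replicate 2, 4 and 13 without Atss3 1 h replicate 1, and 5 and 29 without Atss3 1 h replicate 2. At 4, 8.5, 12 and 16 h the counts were 2, 2, 3 and 4, against 590, 1812, 1623 and 438 at an unadjusted p under 0.05. QQS was called at each of these times, with 3.94, 3.33, 2.77 and 3.90 log2 (SE 0.330 each). AT5G19240 was higher by 1.63 at 12 h (SE 0.183, adjusted p = 0.00711). AT1G06270 was lower by -1.66 at 16 h (SE 0.202, 0.00922), but by -0.17 (adjusted p = 1) with raised signals. With 64 added before log2, the counts at 1 h and 12 h were 3 and 24, and leaving out WT 1 h replicate 1 or Atss3 12 h replicate 1 took them to 92 and 74. QQS missed the threshold at 8.5 h without Atss3 8.5 h replicate 1 (adjusted p = 0.0522) and at 12 h without either WT array of 12 h or without Atss3 12 h replicate 2 (largest adjusted p = 0.0727).

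The genotype difference changed over the day for 1 probe set, and that call rested on dim signals. The unnamed probe set 266932_s_at differed by -2.82 log2 at 1 h and by 0.43, 0.39, 0.93 and 0.09 at 4, 8.5, 12 and 16 h (interaction adjusted p = 0.0207). It was dim on 15 of 20 arrays, 2 of 2 in each genotype at 1 h, and with raised signals it differed by 0.08 at 1 h (interaction adjusted p = 0.985). The 6 named genes with the smallest interaction p did not pass. They were AT3G19330 (adjusted p = 0.122), AT1G06270 and AT5G19240 (0.144), and AT5G63480, AT5G66740 and AT1G72060 (0.196). An unadjusted p under 0.05 was reached by 1099 probe sets (7.1%), and the call was also lost without the run block, where 0 were called.

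Among probe sets called over time in both genotypes, most peaked at the same harvest in both. The moderated F test over the 5 times called 6836 probe sets in WT (44.2%) and 7424 in Atss3 (48.0%), with 5534 called in both. Of these 5534, 3889 (70.3%) had their highest mean at the same time in both genotypes. The peak came 1 sampled time later in Atss3 for 813 and 1 sampled time earlier for 388, and the difference between these counts was not tested. In WT the peaks fell at 1 h for 1578, at 4 h for 959, at 8.5 h for 1376, at 12 h for 866 and at 16 h for 755.

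Between light (1 and 4 h) and dark (12 and 16 h), AT1G30250 rose by 3.66 log2 and AT3G15630 by 3.56 in WT, over 4 arrays each. COR27 rose, and the clock gene GI (AT1G22770) fell. COR27 was dim on 4 of 4 light arrays in each genotype and GI on 4 of 4 dark arrays, so their sizes as deposited (5.88, SE 0.292, adjusted p = 3.35e-08, and -5.28, SE 0.296, adjusted p = 7.39e-08, in WT) rest on signals of low precision. With signals raised to each array's 40th percentile, COR27 differed by 4.29 in WT and 3.66 in Atss3, and GI by -3.56 and -3.58. By the deposited values the largest rises in WT also included AT4G33980 (6.33, and 2.35 with raised signals), AT2G23910 (6.06, 1.504), AT1G17665 (5.55, 1.198), AT1G29160 (5.28, 0.72) and AT1G07050 (4.97, 2.49), all dim on 4 of 4 light arrays. The largest falls were AT2G15020 (-7.09, and -4.49 with raised signals), AT1G13650 (-6.41, -3.34), AT1G70985 (-5.74, -2.37), AT5G66740 (-5.50, -1.75), AT2G27420 (-5.31, -3.71), AT3G46370 (-4.83, -0.77) and AT5G62210 (-4.64, -1.04), all dim on 4 of 4 dark arrays. Deposited standard errors ran from 0.21 to 0.67 and adjusted p-values from 1.85e-08 to 0.000136, and each was past the threshold with the same sign in Atss3. With raised signals each kept the call in WT (largest adjusted p = 0.00733), and in Atss3 AT5G62210 lost it (-0.39, adjusted p = 0.213).

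**Figure D3:**
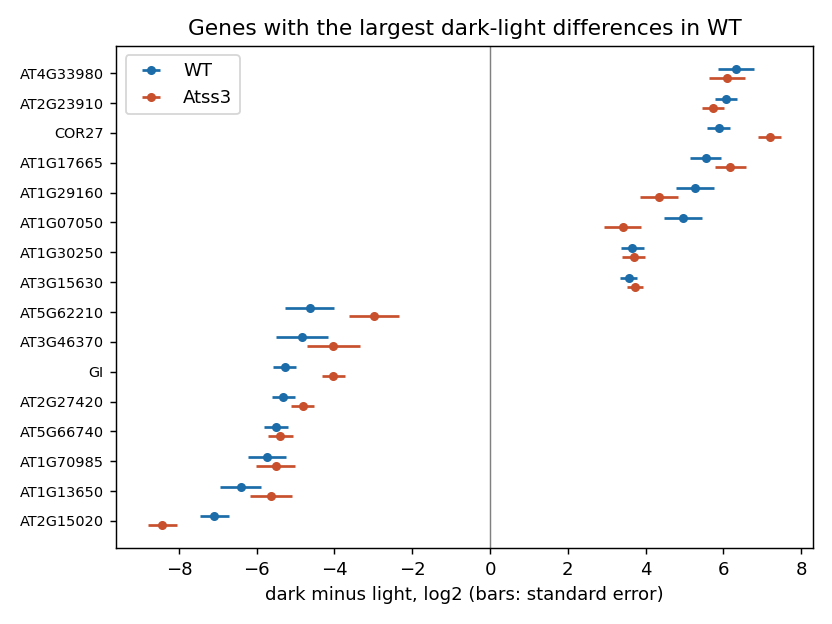
Dark minus light in log2 units for the 8 genes with the largest rises and the 8 with the largest falls in WT, with a point for each genotype and bars for the standard error. Values ran from -7.09 (AT2G15020) to 6.33 (AT4G33980) in WT, and each gene had the same sign in Atss3. The values are as deposited, and for all but AT3G15630 they rest at least in part on signals under the array's 40th percentile, for AT1G30250 on 1 of 4 light arrays in Atss3 only.

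In all, 5338 probe sets were called in WT (3050 higher and 2288 lower in the dark, 1674 by at least 2-fold) and 5923 in Atss3 (3341 higher, 2582 lower, 1870 by at least 2-fold). With arrays centred on their medians the balance turned in Atss3 (2760 higher, 2921 lower) and was nearly even in WT (2629 higher, 2506 lower). Both genotypes called 4197 of them, 2318 higher and 1879 lower, with 0 in opposite directions, where independent lists would share 659 and 382. WT alone called 1141 and Atss3 alone 1726. The difference between the genotypes in this contrast was called for 0 probe sets in limma, with 783 (5.1%) at an unadjusted p under 0.05 against 774 for chance, so genes past the threshold in only 1 genotype are not shown to differ. Across genes the changes correlated at 0.913.

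The measured starch synthesis and light harvesting genes fell in the dark in WT. All 3 measured starch synthesis genes fell: APL3 by -1.20 (SE 0.110), SBE2.2, a starch branching enzyme, by -0.72 (SE 0.143), and AT5G39790, which brings granule-bound starch synthase to starch, by -0.73 (SE 0.115), with 3 of 3 when adjusted over the list alone (camera adjusted p = 0.00527; p = 0.0163 with an estimated correlation, adjusted p = 0.147). All 4 light harvesting and photosystem genes fell, with LHCB4.2, an antenna protein of photosystem II, at -1.83 (SE 0.124), PSAE-1 at -0.62 (SE 0.154) and LHCB4.1 at -0.49 (SE 0.115), and 4 of 4 when adjusted over the list alone (adjusted p = 0.00527; p = 0.0863 with an estimated correlation). In Atss3 these lists were also called (adjusted p = 0.0123 and 0.00561; with an estimated correlation p = 0.0236 and 0.0794, adjusted p = 0.212 and 0.238, so neither was called), as was the Calvin cycle (adjusted p = 0.0328; p = 0.115 with an estimated correlation), with SBPASE at -0.64 (SE 0.101), RCA, rubisco activase, at -0.59 (SE 0.110) and PRK at -0.44 (SE 0.142). After quantile normalization only starch synthesis was called in each genotype. The light harvesting median went from -0.56 to -0.28 in WT (adjusted p = 0.0549) and from -0.63 to -0.21 in Atss3 (0.0728), and the Calvin cycle median in Atss3 from -0.59 to -0.11 (0.722). In WT the Calvin cycle list missed the threshold (adjusted p = 0.054), with 2 of 3 genes called over all genes and 3 of 3 when adjusted over the list alone.

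Of 3 starch breakdown genes, 2 rose in each genotype, and the list missed the threshold. PWD, phosphoglucan water dikinase, rose by 1.61 in WT (SE 0.168, adjusted p = 1.38e-05) and 1.35 in Atss3 (SE 0.168), and DPE1 rose by 1.03 (SE 0.137) and 1.15 (SE 0.137), with AMY1 at 0.24 (adjusted p = 0.658) and list adjusted p-values of 0.054 in WT and 0.0575 in Atss3. The list was called in Atss3 with arrays centred on their medians (0.0397, against 0.0519 in WT) and in both genotypes with raised signals (0.0495 in WT and 0.0428 in Atss3). Of 5 genes induced by carbon starvation, 3 rose and 1 fell in WT (adjusted p = 0.368). AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, rose by 1.91 (SE 0.175), ATL8 by 1.36 (SE 0.223) and MCCA, of leucine breakdown, by 0.88 (SE 0.172), while AT1G70000 fell by 1.09 (SE 0.146). When adjusted over the list alone, 4 of 5 passed. Of 4 sucrose genes, 2 rose in WT, SWEET11 by 0.73 (SE 0.145) and AT1G62660, an acid invertase, by 1.82 (SE 0.223), and 3 passed when adjusted over the list alone (list adjusted p = 0.558). UGT78D2, which adds glucose to flavonols, fell by 2.38 (SE 0.198) and SAG29 by 2.68 (SE 0.417, and -1.70 with raised signals), while the anthocyanin, senescence and cold lists were not called (adjusted p = 0.414, 0.952 and 0.918), with 1, 3 and 0 of 3 members passing when adjusted over the list alone.

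Among the families, most nuclear photosystem genes fell and most autophagy genes rose in the dark in WT, though both calls were lost with an estimated correlation. Of 8 nuclear-encoded photosystem genes 7 fell, with PSBY at -0.99 (SE 0.122) and PSAN at -0.99 (SE 0.170) beside LHCB4.2 (adjusted p = 0.00141; p = 0.108 with an estimated correlation). Of 10 genes of the ATG8 pathway, whose proteins mark autophagosomes, 7 rose, with ATG8D at 1.73 (SE 0.114), ATG8E at 1.67 (SE 0.149) and ATG8H at 0.76 (adjusted p = 0.00705; p = 0.0914 with an estimated correlation). In Atss3 both were called too (adjusted p = 0.00108 and 0.00306; p = 0.103 and 0.0759 with an estimated correlation). The SWEET sugar transporters were also called in Atss3 (6 of 10 fell and 1 rose, median -0.83, adjusted p = 0.0468; p = 0.0933 with an estimated correlation). The call was lost after quantile normalization (median -0.79, adjusted p = 0.0526), with arrays centred on their medians (-0.89, 0.0723) and with raised signals (-0.39, 0.0838). Among the members, SWEET13 differed by -2.77 (SE 0.252), SWEET2 by -1.31 (SE 0.129) and SWEET17 by -1.08 (SE 0.135). In WT, 6 of the 10 fell and 2 rose, with SWEET13 at -2.88 (SE 0.252), and the family missed the threshold (adjusted p = 0.0916).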

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

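The tests of the plastid pattern on the WT arrays of run 1 and on genotype were chosen only after the result was seen. They included a rise of the same size in both runs. The test of the cold pattern on the WT arrays of run 1 was chosen then too. So were the fit with the GAPDH ratio as a covariate, the raising of dim signals and the check of signs kept at 1 h. The conditions on 95% intervals and on the estimated correlation were also added then, so that a wide spread left an explanation open.

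Among 35 genes named for size or p, the 10 Atss3 minus WT differences of 4 genes held a pair of arrays set apart from the rest, and so did 9 of 164 list and family members, where chance sets apart about 1 in 20 groups. AT5G62210 differed by -4.518 log2 in the pair of 1 h run 2. AT3G46370 differed by 3.746 in the pair of 8.5 h run 2. AT4G33980 differed by 2.364 in the pair of 1 h run 2. AT1G07050 differed by 5.338 in the pair of 1 h run 1. All 4 genes had signals near the floor on some arrays. Their lowest WT signals were 3.8, 1.6, 2.8 and 1.5, where the lowest 40th percentile of any array was 80.5. AT4G33980 and AT1G07050 were dim on all light arrays of WT, so the sizes of these pairs are of low precision. The genotype difference of probe set 266932_s_at changed over the day (interaction adjusted p = 0.0207), but not with its dim signals raised (0.985). The log2 ratio of the 3' to the 5' GAPDH control signal, used for genes only as a covariate in an alternative fit, was higher in Atss3 by 0.318 (0.403 ± 0.14 against 0.084 ± 0.247, SD, 10 arrays each, 9 of 10 pairs, exact permutation p = 0.00586, adjusted p = 0.0176 over 3 measures). That p takes the 10 pairs as independent. The difference came largely from the WT arrays of run 1, with a mean of -0.132. WT had 0.301 in run 2, and Atss3 had 0.378 and 0.427 in runs 1 and 2. A genotype difference apart from the runs is therefore not shown by that p. The actin 3' to 5' ratio differed by -0.198 (higher in 5 of 10 pairs, exact permutation p = 0.352). The 25S ribosomal RNA signal differed by -0.164 (higher in 6 of 10 pairs, exact permutation p = 0.74).

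Plastid-encoded transcripts had a median of 0.36 log2 above WT in Atss3 over both runs together, but in run 2 their median difference was -0.223, and the 5 WT arrays of run 1 had the lowest GAPDH ratios. A difference of those 5 WT arrays in RNA quality or labelling may account for the pattern. The log2 actin 3' to 5' ratio did not set these arrays apart, however. It ran from 2.519 to 3.43 on them and from 2.426 to 3.051 on the WT arrays of run 2. The GAPDH ratio itself differed by genotype, mainly through the WT arrays of run 1. With it as a covariate 4 families were called for genotype, all as lower in Atss3. The plastid photosystem and ribosomal medians were then -0.13 and 0.005 without a call, and the cold median was -0.267 (adjusted p = 0.245). The mean over pairs was 0.957 in run 1 (95% interval 0.603 to 1.31) and -0.319 in run 2 (-0.736 to 0.099, with 0 of 5 pairs above 0). The intervals do not overlap, and the upper limit of 0.099 in run 2 lies below the reported 0.36. Each interval covers only the scatter among the pairs of its run, not a shift shared by the arrays of 1 genotype in that run. A genotype rise of the reported size in both runs therefore could not be decided on. A smaller effect or one that differs between the runs stays open as well. Carry-over of RNA without a poly(A) tail could not be told apart: the differences of the 25S ribosomal RNA and of the plastid genes had Pearson r = 0.168 over 10 pairs (permutation p = 0.635, 95% interval -0.516 to 0.721) and Spearman rho = -0.018 (permutation p = 0.973), with r = 0.128 without the 2 pairs farthest from the median and too few pairs within a run.

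The cold and dehydration family was called as lower in Atss3 (adjusted p = 0.0129) with 0 of 9 members called, and the call was lost with an estimated correlation (adjusted p = 0.967), with fry (0.273) and with arrays centred on their medians (0.052, where the median was -0.317 against -0.247). The median of the members was below 0 at 5 of 5 times (-0.085, -0.146, -0.228, -0.294 and -0.233). This argues against a constant shift of harvest time between the genotypes as the whole cause. The family was called from the mean over these same times, so the test is not independent, and shifts that differ between the times stay open. COR27 alone could not be told apart: without it the other 8 genes had a median of -0.246 and an unadjusted camera p of 0.0162 (0.00121 with it; adjusted p = 0.13), but that p assumed a correlation of 0.01 where 0.151 was estimated for the family, the estimated correlation gave p = 0.0946, and the mean over pairs was -0.182 (95% interval -0.398 to 0.034). A difference of the WT arrays of run 1 stays open: the median in run 2 was -0.211, with a 95% interval from -0.414 to 0.125 for the mean over its pairs, and the WT arrays of run 1 were not higher than those of run 2 (10.413 and 10.432, while Atss3 had 10.017 and 10.282), but the 95% interval of that difference, -0.463 to 0.425, reaches the size of the run 1 difference, -0.395. A lower level in the mutant leaves may be a biological difference, which remains a hypothesis.

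Without Atss3 12 h replicate 1, more probe sets were called at 12 h than at 1 h. With all arrays, the highest count was that of 1 h. With each of the 4 arrays of that time left out in turn, all 17 reported probe sets kept their sign. Whether a single array was the source of the higher count could not be told from these fits. Each leaves 1 array in its group, so the scatter of that group no longer enters the estimate of the spread. A count can stay high or rise for that reason alone. Dim signals stay open as a source: 8 of the 17 lay under their array's 40th percentile on all arrays of 1 h, 11 were called with signals raised to that percentile, and with 64 added before log2, 3 were called at 1 h and 24 at 12 h. A slightly different harvest time could not be told apart: 7 of the 17 differed as a lead of Atss3 along the change from 16 h to 4 h would give and 10 as a lag, and the 95% interval of the share that lagged, 32.9% to 81.6%, reaches the share such a shift would give. The response of the mutant to the start of the light may be a source as well.

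Other splits of the arrays were compared with the real ones. For the genotype effect over the day, 4 of 100 splits that exchanged genotypes within pairs, the real one included, called at least the real 3 probe sets, and the highest other called 18. For unadjusted p under 0.05, 2 of 100 splits reached the real 2123, with 2464 as the highest other. Chance can be excluded for both counts only if the pairs are independent, and variation shared by the pairs of a run is not covered. The split with 18 exchanged the genotypes in run 2, was included on purpose, and points to a difference between the runs in the genotype effect, which was called for 83 probe sets. On the 8 arrays of each genotype taken alone, dark against light called 2925 probe sets in WT and 2321 in Atss3. A count as large came in 1 of 35 splits each, with highest other counts of 30 and 1. Replicate arrays share a harvest time, and most splits part them, so a chance difference among the harvest times is not excluded.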

How the results depend on the processing

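The covariate, the threshold of 0.1, the 5 WT arrays of run 1 left out, runs alone for lists and families, signals raised to the array's 40th percentile, and all alternatives for the families were chosen only after the result was seen. The signal of SS3 could not be run. Of 223 counts under alternatives other than leaving out 1 array, 164 stayed within 1.5 times the reported count and 59 moved. Of 5184 results on single genes, called or not, 128 lost the call and 33 gained it. Another 235 differed in sign but were past the threshold in neither setting. A further 3 past the threshold reversed, all with dim signals raised to the array's 40th percentile. These were AT3G19330 at 1 h (0.08, adjusted p = 0.936) and for dark minus light in WT (-0.01, adjusted p = 0.966), and NRPD7 at 1 h (0.08, adjusted p = 0.932). QQS stayed past the threshold over the day in 35 of 35 alternatives (3.24 to 3.66 log2) and 262809_at in 34 of 35 (-2.56 to -1.85), but 245882_at in 12 of 34 (0.31 to 0.95 log2, adjusted p from 0.0084 to 0.566). The number of arrays limits precision.

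Values are numbers of probe sets, lists or families called; the reported counts were 3 over the day, 17, 2, 2, 3 and 4 at the 5 times and 1 for the interaction. For dark minus light they were 2 lists and 2 families in WT and 3 and 3 in Atss3, and 3 families and 0 lists were called for genotype. Without the replicate block, 8.5 h gave 1, the interaction 0 and families for dark minus light in WT 1. With the replicate block as random, 12 h gave 5 and families for dark minus light in WT 1. Quantile normalization gave 11 over the day (4 higher, against 2 of 3 reported), 5 at 8.5 h, 5 families for genotype, and 1 list each for dark minus light in WT and in Atss3. Arrays centred on their medians gave 5 over the day (2 higher, 3 lower) and 4 lists for dark minus light in Atss3, starch breakdown being the addition. Signals raised to the array's 40th percentile gave 11 at 1 h, 2 at 16 h and 0 for the interaction. With 16 added before log2, the day gave 7, 1 h 7, 8.5 h 1, 12 h 5 and the interaction 0. With 64 added, the day gave 8, 1 h 3, 8.5 h 1, 12 h 24, 16 h 2 and the interaction 0. No filter on dim probe sets gave 1 at 8.5 h, 2 at 16 h, 0 for the interaction and 4 lists for dark minus light in WT. Only the brighter probe sets gave 10 at 1 h, 4 at 4 h, 0 for the interaction and 5 families for genotype. An intensity trend gave 4 at 4 h, 9 at 12 h, 0 for the interaction and 4 lists for dark minus light in WT. Run 1 alone gave 86 over the day and 6 families for genotype. The threshold of 0.1 gave 8 over the day. With an estimated correlation 0 lists and 0 families were called for dark minus light in WT and in Atss3, and 0 families for genotype. With fry, 7 lists and 15 families were called for dark minus light in WT, 13 families in Atss3 and 0 for genotype. With the GAPDH ratio as a covariate 4 families were called for genotype, all lower in Atss3 and none of them among the 3 reported. With the 5 WT arrays of run 1 left out, the day gave 5, 1 h 7, 8.5 h 5, 12 h 5, 16 h 2, the interaction 0, dark minus light in WT 2506, the time course in WT 2780, lists for dark minus light in WT 4 and families for dark minus light in Atss3 6; fewer arrays were used there, and the 3 families called for genotype were plastid families lower in Atss3, where 2 were higher as reported. For the genotype difference over the day, that last fit gives the difference of run 2 alone. Elsewhere the cause was not tested.

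With each array left out in turn, a lone array of a group was assumed to vary like the other groups. The day gave 2 to 13 (13 without WT 8.5 h replicate 1, 9 without WT 1 h replicate 1, 8 without WT 1 h replicate 2 or WT 16 h replicate 1, 6 without WT 4 h replicate 2 or Atss3 1 h replicate 2, 5 without Atss3 4 h replicate 2 or Atss3 8.5 h replicate 2). At 1 h the counts were 10 to 92 (92 without WT 1 h replicate 1, 34 without Atss3 1 h replicate 2, 27 without WT 1 h replicate 2, 10 without either Atss3 12 h array, 11 without either Atss3 4 h array), at 4 h 2 to 4 (4 without either WT 1 h array, Atss3 1 h replicate 1 or Atss3 4 h replicate 2), at 8.5 h 1 to 20 (20 without WT 8.5 h replicate 1, 15 without Atss3 8.5 h replicate 2, 5 without WT 8.5 h replicate 2, 4 without either WT 1 h array, and 1 without any array of 12 or 16 h, either WT 4 h or Atss3 1 h array, or Atss3 8.5 h replicate 1), at 12 h 2 to 74 (74 without Atss3 12 h replicate 1, 11 without WT 12 h replicate 2) and at 16 h 1 to 5 (1 without WT 16 h replicate 1, 2 without WT 16 h replicate 2). Dark minus light gave 4087 to 5343 in WT, 4743 to 6181 in Atss3 and 0 to 2 for the difference (2 without either Atss3 1 h array or Atss3 16 h replicate 1, 1 without WT 1 h replicate 1). The interaction gave 0 to 5 (5 without Atss3 1 h replicate 2, 4 without WT 8.5 h replicate 2, 3 without Atss3 16 h replicate 1). It gave 2 without Atss3 8.5 h, Atss3 12 h, WT 1 h, WT 4 h or WT 8.5 h replicate 1, or Atss3 16 h or WT 16 h replicate 2. It gave 0 without either Atss3 4 h array or WT 12 h array, or without Atss3 8.5 h, Atss3 12 h, WT 1 h or WT 4 h replicate 2, or WT 16 h replicate 1. The time course gave 5769 to 6795 in WT and 5952 to 7763 in Atss3. Lists gave 0 to 2 for genotype (2 without Atss3 12 h replicate 1), 2 to 4 in WT (4 without replicate 1 of WT 1 h, 4 h or 12 h) and 2 to 4 in Atss3. Families gave 0 to 5 for genotype (0 without Atss3 16 h replicate 1, 1 without replicate 1 of WT 1 h or 4 h, 5 without replicate 2 of Atss3 4 h, Atss3 16 h, WT 4 h, WT 8.5 h or WT 16 h), 2 to 3 in WT and 2 to 4 in Atss3. The cause was not tested.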

Other observations

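Some members of further families changed between light and dark in WT without the families being called as sets, in a contrast that called 34.5% of all probe sets. Among 13 expansins, which loosen cell walls, 3 rose and 4 fell (camera adjusted p = 0.861), with EXPA16 at 2.75 log2 and EXPA8 at -1.60. Among 6 xyloglucan endotransglucosylases, which cut and rejoin wall glucans, 3 rose and 2 fell (adjusted p = 0.852), with XTH32 at -2.72; the rise of XTH33 was lost with signals raised to each array's 40th percentile (0.18, adjusted p = 0.444). Of 5 WRKY transcription factors 3 rose (adjusted p = 0.2), with WRKY6 at 2.23 (0.92 with raised signals). Of 11 genes of the cytochrome P450 71B family 3 fell (adjusted p = 0.126), with CYP71B26 at -4.14. Of 8 tau-class glutathione transferases 3 fell (adjusted p = 0.0916), with GSTU23 at -1.47 (-0.64 with raised signals).

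Of 11 citrate cycle and citrate lyase genes 5 rose in the dark in WT (camera adjusted p = 0.33), with IDH-VI at 0.65 and cICDH at 0.76. Of 8 genes grouped as the mitochondrial leucine and electron-transfer flavoprotein pathway 4 rose (adjusted p = 0.162), with ETFBETA at 0.46 and ALDH6B2 at 0.46. Among 28 UGT glycosyltransferases 9 rose and 8 fell (adjusted p = 0.852), with UGT76C2 at 1.42. Among 7 calmodulin-like genes 3 rose and 1 fell (adjusted p = 0.573), with CML42 at 1.27.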
